A study of Mus musculus with 6 samples.

How the data were processed

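RNA was measured in 6 libraries of Lewis lung carcinoma cells, 3 with a scrambled and 3 with a Urod-directed inducible shRNA, grouped by their titles in the labels. Per the labels' protocols, total RNA was column-purified with DNase digestion, polyadenylated RNA was selected, and strand-specific libraries were sequenced as 51-bp single-end reads. Per the labels' protocols, trimmed reads were mapped to mm10 with TopHat, alignments of mapping quality under 10 were discarded, and abundance was estimated with Cufflinks and Cuffdiff (version 2.1.1 per the submitters' processing notes). Discarding low mapping quality can lower genes with near-identical copies, which was not tested here, and the values of such genes are treated as uncertain. Gapdh stood at 7.43 TPM in scrambled libraries. The use of strand in counting is not given in the sources used here.

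The deposited per-sample table is named as normalized counts, but each column sums to 1000000, and log2 of its values minus the authors' log2 CPM follows log2 transcript length (Pearson r = -0.897 across 10030 genes, which are not independent replicates). The deposited values were therefore read as TPM that the authors had made from the mapped reads, scaled per gene length and per library; how reads were assigned to genes is not given in the sources used here, and the test planned for per-length units was used. The authors' deposited comparison table holds log2 fold changes, log2 CPM, a likelihood ratio score, p-values and FDR, per the file headers. Its log2 fold changes matched log2 ratios of mean TPM with a median difference of -0.00666 and an SD of 0.0122 over 11979 genes. Its column names are those of a likelihood ratio test while the labels name Cuffdiff, and the test behind it is not given in the sources used here. The authors' deposited pathway list repeats the values of both tables for 451 genes.

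Of 19617 rows, 27 carry a calendar date in place of a gene name, as spreadsheets make of some symbols. They hold 0.231% to 0.241% of TPM per library and were left out of tests. Genes were tested if their mean over the 6 libraries was at least 1 TPM, which left 11980. Values were transformed as log2(TPM + 1), which understates the change of low genes, and fitted with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a variance trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Of the 27 gene lists fixed before the data were examined, 26 had tested members and were compared with other genes by camera with a correlation of 0.01, adjusted over lists. An estimated correlation and fry were alternatives. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

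Named genes were chosen by a rule fixed before the data were examined: Urod, every heme synthesis enzyme (1 of them is not reported here), the 10 largest rises and 10 largest falls among called genes whose groups do not overlap and whose mean is at or above the median of tested genes (28.4 TPM), leaving out joined names, gene models, microRNA and snoRNA genes, and up to 4 members per list with the smallest adjusted p. Gapdh, Rn45s and other genes outside this rule, among them Dnajb9 and Fgf21, were chosen after their values were seen. Coordinates are those of GENCODE M21 on GRCm38, the assembly that mm10 names.

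The procedure was tested on simulated data with 200 genes changed by 4 fold sizes, and a further list of 20 genes raised 1.5-fold, among 11980 for the same comparison. Of the 200 it recovered 74% of genes changed 1.25-fold, 80% at 1.5-fold, 92% at 2-fold and 100% at 4-fold, that is 37, 40, 46 and 50 genes. Of 204 calls in all, 17 fell on the list of 20 and 14 on unchanged genes. In the data 74.7% of tested genes were called, far more than were changed in the simulation. The adjustment was therefore stricter in the simulation, and its recovery rates do not carry over to the data. TPM keep no counts, so no interval for counting error can be given, and relative depth was read from 3544 genes with a mean under 0.05 TPM. Alternatives were other pseudocounts, filters, scalings and variance settings, a replicate block, and leaving out each library. Settings added after the data were seen removed a length and GC trend, small RNA and Rn45s rows, or the chaperone list.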

Results

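RNA was sequenced from Lewis lung carcinoma cells, a transplantable mouse lung tumour line, that carried a doxycycline-inducible short hairpin RNA (shRNA) delivered by lentivirus. The hairpin either had a scrambled sequence (3 libraries) or was directed at Urod (3 libraries), and all cells received 2 ug/mL doxycycline for 4 days. Urod encodes uroporphyrinogen decarboxylase, an enzyme of the heme synthesis pathway. Values are TPM, a transcript abundance scaled for transcript length and for the library total, so absolute read depth is unknown. The step between the lowest values of rarely detected genes put the scrambled libraries at 72.9%, 77.2% and 81.9% of the depth of Urod shRNA replicate 1, and the other Urod shRNA libraries at 95.6% and 85.7%. Libraries of the same group correlated across genes with r between 0.996 and 0.998, and libraries of different groups with r between 0.958 and 0.960. Nothing in the labels says whether the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

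The first question was whether the hairpin lowered its target. Urod stood at 95.2, 89.9 and 92.1 TPM in the scrambled libraries and at 5.71, 5.21 and 5.35 TPM in the Urod shRNA libraries. The mean fell from 92.4 ± 2.66 TPM to 5.42 ± 0.254 TPM (SD, n = 3 each), which is 5.87% of the scrambled level. On the log2(TPM + 1) scale the change was -3.86 (SE 0.05, limma, adjusted p = 8.22e-09). Urod (ENSMUSG00000028684.14) is a protein-coding gene on chromosome 4, from 116989965 to 116994413 on the minus strand of GRCm38. The authors' deposited table gives a log2 fold change of -4.08 for it.

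Around this step, the transcripts of the other heme synthesis enzymes moved in both directions. Alas1, the first and rate-limiting enzyme of the pathway outside red cell precursors, rose 2.18-fold, from 79.0 ± 2.80 to 172 ± 3.39 TPM (SD, n = 3 each). Uros, which acts just before Urod, rose 1.81-fold. Ppox fell by 0.74, Fech by 0.31 and Alad by 0.16 on the log2 scale, and Cpox, which acts just after Urod, stood at 51.2 ± 0.201 and 51.5 ± 1.23 TPM (SD, n = 3 each; limma, adjusted p = 0.855). The calls of these enzymes were the same when adjusted over the list alone. The list as a set did not pass the test (camera, adjusted p = 0.603), and its median and mean differed in sign. Alas1 (ENSMUSG00000032786.16) lies on chromosome 9 from 106233455 to 106248654.

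**Figure D1:**
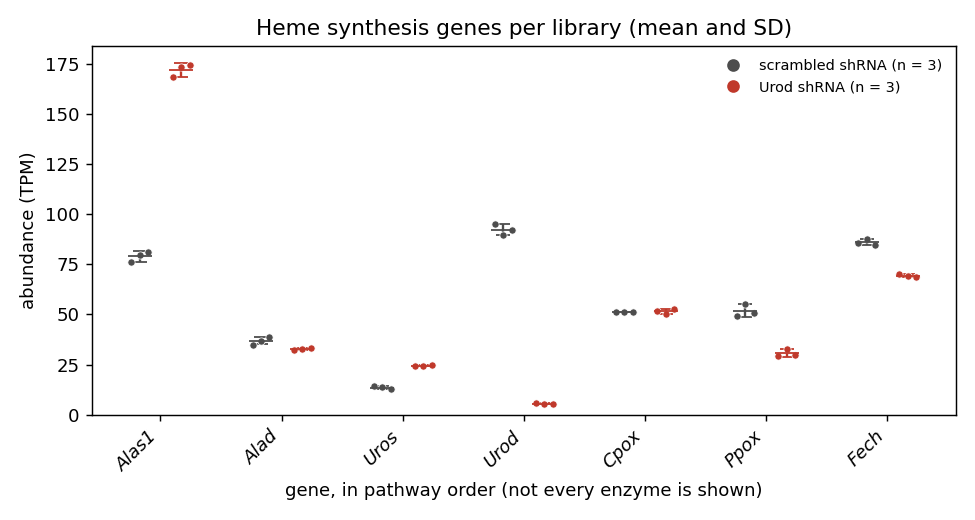
Abundance of Urod and 6 other heme synthesis genes in TPM (vertical axis), in pathway order with not every enzyme shown (horizontal axis), for the scrambled (grey) and Urod shRNA (red) libraries; points are libraries, and bars are the mean and SD of 3. Urod falls from 92.4 to 5.42 TPM and Alas1 rises from 79.0 to 172 TPM.

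Genes that handle heme, porphyrin and iron also changed without a common direction. Hmox1, the inducible enzyme that breaks heme down, rose 2.29-fold, while the porphyrin transporter Abcb6 fell by 0.73 and the heme transporter Slc48a1 by 0.64 on the log2 scale. In that list 6 of 18 measured genes rose and 7 fell (camera, adjusted p = 0.839). Among iron genes, the transferrin receptor Tfrc rose by 0.47 and the metal transporter Slc39a14 by 0.77, whereas Hfe fell by 1.13 and Fbxl5, part of the ubiquitin ligase that degrades an iron regulatory protein, by 0.99. There 9 of 21 rose and 7 fell (camera, adjusted p = 0.810), and the median (0.07) and mean (-0.05) differed in sign. Of 16 other hemoproteins 4 rose and 9 fell (camera, adjusted p = 0.166), among them the cyclooxygenases Ptgs1 (-0.83) and Ptgs2 (-0.81) and, upward, the microRNA processing factor Dgcr8 (1.15).

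The design's main question was which transcripts differ between cells with the Urod hairpin and cells with the scrambled one. Differences reached most of the genes tested. With only these 2 groups, all on doxycycline, loss of Urod cannot be told apart from other differences between the 2 cell populations. Nor can a change be placed in one population rather than the other. Of 11980 genes tested, 8945 changed (74.7%), 4609 upward and 4336 downward, and 902 of them changed at least 2-fold, 328 upward and 574 downward (limma on log2(TPM + 1), adjusted p under 0.05). The median size of a called change was 0.44 on the log2 scale. The values of the groups did not overlap for 77.3% of genes, against 10% by chance for 3 against 3. With a pseudocount of 10 the number changed at least 2-fold was 244, and among genes with a mean of at least 10 TPM it was 518.

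The deepest fall among the better expressed genes was that of Txnip, the thioredoxin-interacting protein and a sensor of glucose supply, which dropped 20.7-fold, from 1339 ± 16.7 to 64.6 ± 2.68 TPM (SD, n = 3 each; log2 change -4.35, SE 0.04; limma, adjusted p = 2.21e-09). Txnip lies on chromosome 3 from 96557957 to 96561883. The other large falls were those of Akr1cl, the prostaglandin D2 synthase gene Ptgds, the neutrophil chemokine Cxcl1, the matrix protein gene Tgfbi, Prss35, Adck3, Hspa5 and Wfdc2, from 11.3-fold for Akr1cl to 5.16-fold for Wfdc2. Among the same genes, those with a mean at or above the median of tested genes (28.4 TPM), the largest rises were smaller than the fall of Txnip. Fgd3, an exchange factor for a small GTPase, rose 6.95-fold, from 8.55 ± 0.360 to 59.5 ± 6.48 TPM (SD, n = 3 each), Tmem165, a Golgi membrane protein, 5.13-fold, the adhesion receptor gene Gpr56 4.31-fold, and Nampt, the rate-limiting enzyme of NAD salvage, 4.04-fold. Twf2, Heatr3, Cth, Smim4, Spink2 and Ddx39 followed, at 3.67-fold to 3.22-fold. Larger rises occurred under that level, such as that of Etl4, chosen after its values were seen, which rose 27.7-fold, from 0.619 ± 0.0364 to 17.2 ± 1.31 TPM (SD, n = 3 each).

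**Figure D2:**
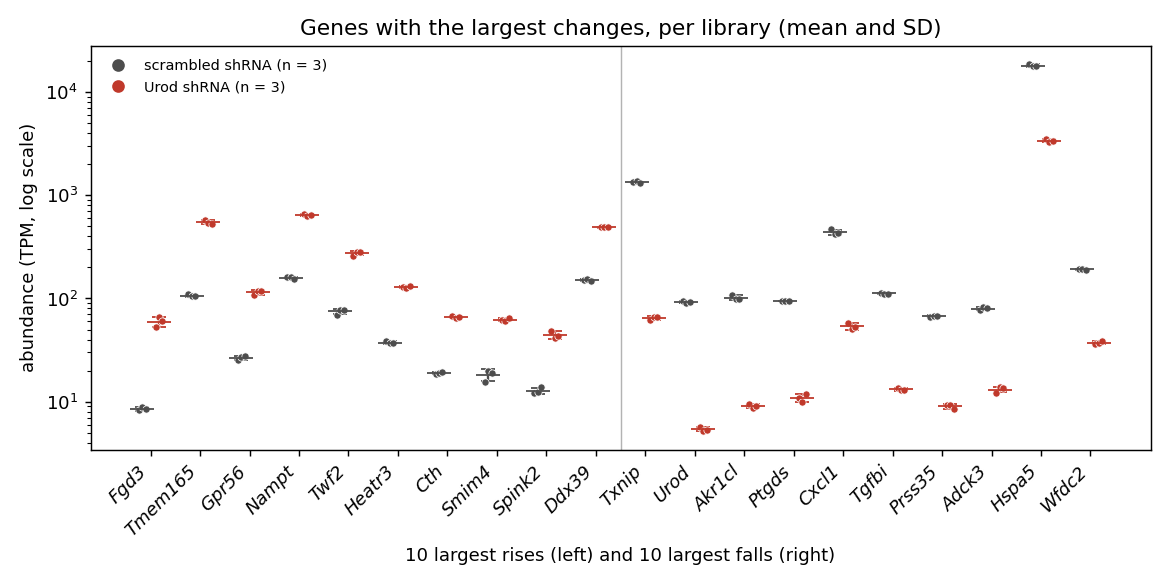
Abundance in TPM on a log axis of the 10 genes with the largest rises and the 10 with the largest falls among better expressed genes, per library (points), with mean and SD of 3; grey is scrambled, red is Urod shRNA. Txnip drops from 1339 to 64.6 TPM and Fgd3 rises from 8.55 to 59.5 TPM.

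Gene lists fixed before the data were examined were then compared with all other tested genes. Counts cover tested members only, and some lists lost many. Tested were 5 of 16 leukocyte and endothelial markers, 6 of 16 epithelial markers, 5 of 10 aryl hydrocarbon receptor targets and 16 of 31 other hemoproteins. Of 26 lists with measured members, 11 passed the test (camera with a preset correlation of 0.01, adjusted p under 0.05), 3 upward and 8 downward. With an estimated correlation 0 passed. Among the 11, the estimate lay under 0.01 for the inflammatory (-0.019) and sterol synthesis (-0.023) lists and above it for the others. A higher correlation between genes therefore does not account for the whole loss. Adjusted over the list alone, the counts of changed members were equal to those over all genes for 23 lists. The exceptions were 1 more member upward among the endoplasmic reticulum chaperones, 1 more downward among interferon-stimulated genes and 1 more upward among mesenchymal genes. Beside all of these groups, Rn45s, the ribosomal RNA precursor, stood at 1313 ± 181 TPM in scrambled and 3782 ± 297 TPM in Urod shRNA libraries (SD, n = 3 each).

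**Figure D3:**
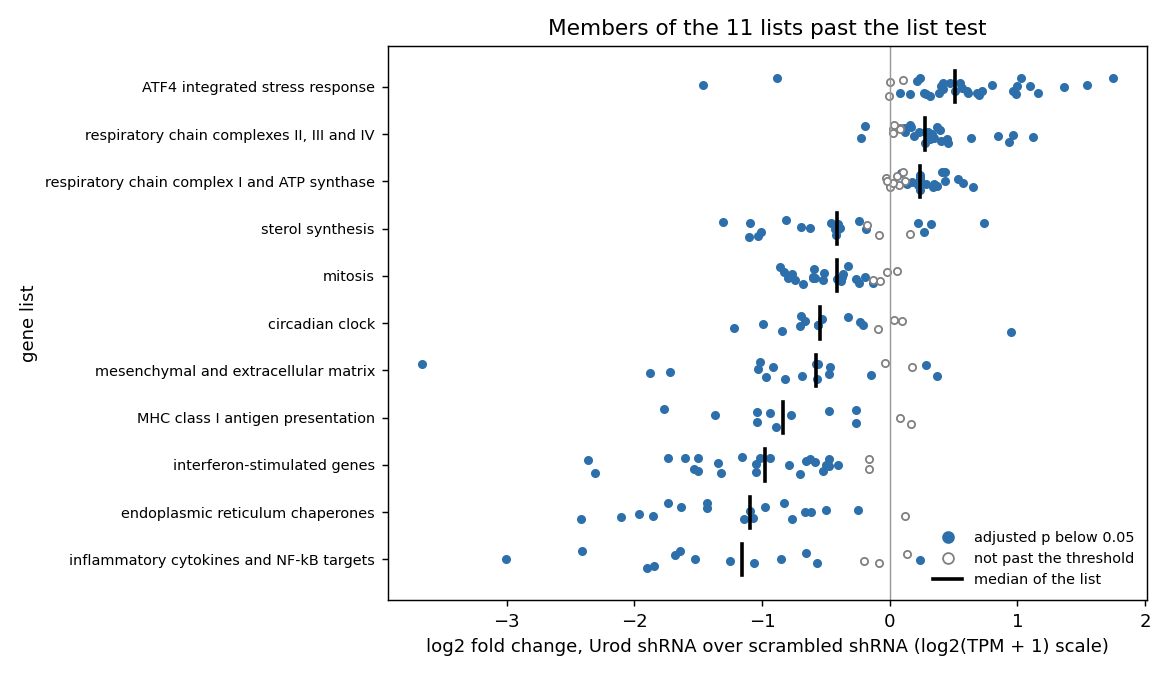
Log2 fold change of each member (points) of the 11 lists past the list test, Urod shRNA over scrambled shRNA on the log2(TPM + 1) scale; filled points passed the gene test, open points did not, and black bars are list medians. The chaperone, interferon and inflammatory lists have medians of -1.10, -0.98 and -1.15.

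Chaperones of the endoplasmic reticulum and other genes of its unfolded protein response fell together. They were fixed as 1 list, called the chaperone list here, though members such as Xbp1 (-0.77) and Sel1l (-0.98) are not chaperones. Of 19 measured, 18 fell and 0 rose, with a median log2 change of -1.10 (camera, adjusted p = 1.93e-08; adjusted p = 0.149 with an estimated correlation). Hspa5, the major chaperone of that compartment, fell 5.34-fold, from 17982 ± 483 to 3370 ± 96.9 TPM (SD, n = 3 each), which took it from between 1.77% and 1.85% of all TPM to between 0.329% and 0.348%. The disulfide isomerases Pdia4 (-2.11) and Pdia6 (-1.63) and the cochaperone Sdf2l1 (-1.74) fell with it, and Dnajb9 (0.12, limma, adjusted p = 0.0601) did not pass. Hspa5 lies on chromosome 2 from 34771970 to 34777547.

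Targets of ATF4, the transcription factor of the integrated stress response, went the other way. Of 35 measured, 30 rose and 2 fell, with a median of 0.51 (camera, adjusted p = 9.13e-07; adjusted p = 0.153 with an estimated correlation). The cysteine-forming enzyme Cth rose by 1.75, the glutathione-degrading Chac1 by 1.55 and the serine synthesis enzyme Psph by 1.37. Ddit3, which encodes the stress factor CHOP, fell by 1.46, and Fgf21 fell by 0.88. Heat shock genes were split, with 6 of 13 up and 5 down (camera, adjusted p = 0.957, median 0.04, mean -0.14). Among them were Cryab (-2.11), Hspa8 (-0.59), Hspb1 (-0.66) and Hsph1 (0.47). This list was fixed as cytosolic but holds the mitochondrial chaperonins Hspd1 (0.56) and Hspe1 (0.31) among the genes that rose.

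Interferon and inflammatory genes fell. Of 26 interferon-stimulated genes, 24 fell and 0 rose, with a median of -0.98 (camera, adjusted p = 2.15e-08; adjusted p = 0.132 with an estimated correlation), including Rsad2 (-2.36), the transcription factor Irf7 (-2.31), Stat2 (-1.34) and the chemokine Cxcl10 (-1.32). Of 12 genes of MHC class I antigen presentation, 10 fell and 0 rose (camera, adjusted p = 0.00148; adjusted p = 0.331 with an estimated correlation), with Psmb9 at -1.77, Tapbp at -1.37, H2-K1 at -0.89 and H2-D1 at -0.78. H2-K1 and H2-D1 are closely similar in sequence and can share reads, so their separate values are uncertain. Of 16 inflammatory cytokines and NF-kB targets, 12 fell and 1 rose (camera, adjusted p = 9.85e-05; adjusted p = 0.132 with an estimated correlation), with Cxcl1 at -3.00, Ccl2 at -1.84, Vcam1 at -1.68 and Nfkbia at -1.25. Markers of leukocytes and endothelium, cells other than the carcinoma line, were mixed beside these groups. Of 5 measured, 2 rose and 3 fell (camera, adjusted p = 0.486): Lyz2 fell from 49.2 to 11.4 TPM and Cd68 from 53.2 to 30.8 TPM, while Cd14 rose from 8.37 to 12.9 TPM and Pecam1 from 4.74 to 7.37 TPM.

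Mesenchymal and extracellular matrix genes fell, 15 of 19 with 2 up (camera, adjusted p = 0.000745; adjusted p = 0.313 with an estimated correlation). Smooth muscle actin Acta2 fell by 3.66, the matricellular gene Cyr61 by 1.88, the intermediate filament gene Vim by 1.02 and Sparc by 0.91. Acta2 belongs to the actins, a family with near-identical copies, and its value is uncertain. Only 6 of the 16 epithelial markers given were tested. Of these 4 rose and 2 fell (camera, adjusted p = 0.486), with Grhl2 at 1.05, Ovol1 at 0.84, Krt8 at 0.54 and Epcam at -0.61. Immediate-early genes were mostly lower without passing as a set, 8 of 13 down and 3 up (camera, adjusted p = 0.134), with Dusp1 at -1.70, Myc at -1.01, Fos at -0.92 and Fosl1 at 0.56.

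Mitotic genes fell while DNA replication genes were split. Of 25 mitotic genes, 21 fell and 0 rose, with a median of -0.41 (camera, adjusted p = 1.95e-06; adjusted p = 0.149 with an estimated correlation), among them the spindle midzone gene Prc1 (-0.86), the mitotic kinase Aurkb (-0.83), cyclin Ccnb2 (-0.74) and topoisomerase Top2a (-0.60). Of 29 replication genes 13 rose and 11 fell (camera, adjusted p = 0.822; median -0.06, mean 0.01), with Tyms at 0.79, Ccne1 at 0.72, Rfc3 at -0.68 and Mcm3 at -0.42. Of 16 p53 targets 5 rose and 7 fell (camera, adjusted p = 0.494), Cdkn1a by 0.67 and Mdm2 by 0.51 upward, and Fas by 2.04 and Ccng1 by 0.89 downward.

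Genes of the mitochondrial respiratory chain rose by small amounts. Of 29 genes of complexes II, III and IV, 22 rose and 2 fell, with a median of 0.28 (camera, adjusted p = 0.00165; adjusted p = 0.149 with an estimated correlation), and of 27 genes of complex I and ATP synthase, 19 rose and 0 fell, with a median of 0.23 (camera, adjusted p = 0.00116; adjusted p = 0.313 with an estimated correlation). Cox10, which carries out a step towards the heme group of complex IV, rose by 0.64, Cyc1 by 0.34, Cox4i1 by 0.33 and Sdhb by 0.28. Ndufs1 (0.44), Atp5b (0.43), Ndufa9 (0.41) and Ndufs8 (0.35) rose with them. Of the 13 genes given for the mitochondrial genome, 0 were in the table. Of 26 glycolysis and hypoxia genes 17 rose and 5 fell (camera, adjusted p = 0.0951). Ldha stood at 0.71, and the prolyl hydroxylases P4ha2 (-1.21) and P4ha1 (-0.85) and the peptide hormone gene Adm (-0.91) were downward. Gapdh (0.58), among those that rose, stood at only 7.43 TPM in scrambled libraries, and its value is uncertain. Of 28 cytosolic ribosomal protein genes 12 rose and 2 fell (camera, adjusted p = 0.130), among them Rps2 (0.44), Rpl19 (0.20), Rpl27 (0.95) and Rpl11 (0.58), and the values of this family are uncertain because it has many pseudogene copies.

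Sterol synthesis genes fell, 16 of 23 with 4 up (camera, adjusted p = 0.00285; adjusted p = 0.149 with an estimated correlation), among them Insig1 (-1.31), Fdft1 (-1.11), Hmgcs1 (-1.10) and Pmvk (-0.69). Of 16 circadian clock genes, 12 fell and 1 rose (camera, adjusted p = 0.00527; adjusted p = 0.450 with an estimated correlation), with Dbp at -0.99, Bhlhe41 at -0.70 and Tef at -0.69, against Clock at 0.95. Of 21 NRF2 antioxidant targets 8 rose and 10 fell (camera, adjusted p = 0.486), with Gsta4 at -1.97, Me1 at -1.15, Gstm1 at -0.86 and Pgd at 0.64. Of 24 autophagy and lysosome genes 13 rose and 8 fell (camera, adjusted p = 0.486), with the proton pump subunits Atp6v1a (1.16), Atp6v1h (1.02) and Atp6v0d1 (0.61) upward and the protease Ctsd at -0.46. Of 5 aryl hydrocarbon receptor targets 1 rose and 3 fell (camera, adjusted p = 0.472), namely Aldh3a1 (-0.97), Tiparp (-0.29), Nqo1 (-0.20) and, upward, Nfe2l2 (0.10), whose call was lost with quantile normalization (0.01), trimmed-mean scaling (0.08), median-ratio scaling (0.09) and without the chaperone list (0.06).

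The authors' deposited table of this comparison was set beside these calls. In the authors' deposited table, FDR was under 0.05 for 11003 of 19617 rows, 5507 upward and 5496 downward. Among the 11980 genes tested here, 9022 were called in the authors' deposited table and 8718 by both, and 100% of the shared calls had the same sign. Another 227 genes were called by limma alone and 304 in the authors' deposited table alone. Both come from the same 6 libraries and are not independent.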

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

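Rows that carry a date in place of a gene name were left out of the limma and list tests, while the authors' deposited table covers them. Of these rows, 5 of the 23 with a date of their own had all 3 Urod shRNA values above all 3 scrambled values, a mean of at least 1 TPM in scrambled libraries and an FDR under 0.05 in the authors' deposited table. This choice was made after the data were seen, and the genes behind the dates were not assigned. The row for month 9, day 15 rose 1.23-fold, from 713 ± 32.4 to 879 ± 49.4 TPM (SD, n = 3 each), and the row for month 3, day 8 rose 1.23-fold, from 33.8 ± 0.609 to 41.7 ± 1.77 TPM. The rows for month 9, day 11 (1.15-fold), month 9, day 9 (1.13-fold) and month 3, day 7 (1.11-fold) rose less. By the same bounds in the other direction 8 rows fell, several of them by more. The row for month 9, day 12 fell from 3.57 ± 0.0590 to 0.252 ± 0.0810 TPM, month 9, day 5 from 34.0 ± 1.5 to 12.8 ± 0.550 TPM, month 9, day 4 from 3.14 ± 0.237 to 1.28 ± 0.0925 TPM and month 9, day 6 from 9.71 ± 0.139 to 6.34 ± 0.392 TPM (SD, n = 3 each). The values of the groups did not overlap for 77.3% of the genes tested, so separation alone does not set these rows apart. No biological explanation was tested for these rows.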

How the results depend on the processing

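Leaving out each library in turn gave 8262 to 9008 changed genes (4259 to 4586 higher, 3988 to 4422 lower), 895 to 928 changed at least 2-fold, a Urod log2 change between -3.89 and -3.84, and 11 lists each time. Across the 12 other gene-level settings, 2 of them added after the data were seen, 6897 to 10286 genes changed, the extremes coming with fewer and more genes tested, and Urod lay between -4.07 and -2.73, the smaller size coming with a pseudocount of 10. In 3 of the 12 fewer genes were higher than lower: 4233 and 4710 without the chaperone list, 4471 and 4546 with trimmed-mean scaling, and 5119 and 5167 with no filter on low values. The number changed at least 2-fold was 244 with a pseudocount of 10, which shrinks low genes by construction, and 518 with a minimum mean of 10 TPM, where fewer genes are tested, and 863 to 1257 under the other 10, highest with a pseudocount of 0.1. The number of lists called was 10 to 12 under 13 settings, 0 with an estimated correlation, also with the length and GC trend removed, and 23 with fry, which asks another question. A further list, glycolysis and hypoxia, passed with no filter on low values (adjusted p = 0.0346). Named genes kept direction and call in 2199 of the refits and lost the call in 4, all of Nfe2l2. With the replicate block 9882 genes changed. Deviations of same-numbered libraries correlated at 0.418, 0.214 and 0.095 across genes. Scrambled replicate 3 correlated best with Urod shRNA replicate 2 (0.203), so the numbers were not taken to pair the libraries. Both libraries numbered 1 did share deviations (0.418). Each correlated negatively with the other replicates of the opposite group (-0.335 to -0.141). Deviations were taken from the group mean, so these negative values are partly built in and add no evidence. What the libraries numbered 1 share is not given in the labels. Requiring q under 0.01 in the authors' deposited table left 8203 shared calls. Of the 10 splits of the 6 libraries into 3 and 3, the real one called 8945 genes and the highest other split 0 (limma, with 9177 and at most 200 at an unadjusted p under 0.05). Only 1 split reached the real count, the real one itself. Every other split mixes both groups on each side, so the group difference enters its spread and few calls can arise. With 10 splits no share under 0.05 is possible. The planned count models were not run because TPM keep no counts. Absolute depth is unknown, which leaves the precision of low genes unstated.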

Other observations

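All gene families in this part were looked at after the values were seen, 32 of them, with p adjusted over the 32, and so were the tests on Rn45s and on gene position and the estimated correlation after the length and GC trend was removed. The splits of the libraries, the length and GC test and the rescaling without chaperones were written before their results were seen. Of the 32 families, 21 passed camera, 12 upward and 9 downward, and 11 did not, among them serpins, tubulins and the hexosamine pathway (adjusted p = 0.587, 0.201 and 0.989); 0 passed with an estimated correlation. Of 29 nucleolar processing factors and RNA polymerase I subunits, 26 rose and 0 fell, with a median of 0.63 (camera, adjusted p = 1.98e-07; adjusted p = 0.0911 with an estimated correlation), among them Nop2 (1.14) and Polr1b (1.16). Of 20 cytosolic aminoacyl-tRNA synthetases, 18 rose and 0 fell (camera, adjusted p = 7.70e-07; adjusted p = 0.127 with an estimated correlation), with Lars and Rars both at 1.05. Some synthetases also belong to the ATF4 list. Of 53 translation initiation factors, 36 rose and 10 fell (camera, adjusted p = 0.000421; adjusted p = 0.197 with an estimated correlation). Of 76 mitochondrial ribosomal proteins, 63 rose and 5 fell, with Mrpl20 at 1.36 and Mrpl33 at -0.62 (camera, adjusted p = 8.73e-08; adjusted p = 0.207 with an estimated correlation). Of 37 proteasome subunits 30 rose and 4 fell (camera, adjusted p = 5.01e-05; adjusted p = 0.280 with an estimated correlation), and the interferon-induced Psmb8 (-1.04) and Psmb9 (-1.77) were among the 4.

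Of 18 collagens 15 fell and 1 rose (camera, adjusted p = 0.000251; adjusted p = 0.436 with an estimated correlation), led by Col3a1 (-1.72) and Col6a3 (-1.56). Of 15 chemokines 12 fell and 2 rose (camera, adjusted p = 0.000117; adjusted p = 0.0911 with an estimated correlation), with Cxcl3 at -2.75 and, upward, Ccl25 at 0.51. Of 16 glutathione S-transferases 11 fell and 3 rose (camera, adjusted p = 0.0110; adjusted p = 0.249 with an estimated correlation), with Gsta2 at -2.47. Some members also belong to fixed lists, such as Col3a1 (mesenchymal), Cxcl1 and Ccl2 (inflammatory) and Gsta4 (NRF2), so these families are not separate evidence.

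Rn45s rose 2.88-fold, from 1313 to 3782 TPM, although polyadenylated RNA had been selected. A candidate biological explanation is more ribosomal RNA synthesis. The nucleolar and polymerase I genes had a median of 0.63 and passed the list test with the preset correlation (camera, adjusted p = 0.0911 with an estimated correlation). This family was picked, and the bound for passing worded, after the values were seen, so the pass cannot test that explanation. Weaker selection of polyadenylated RNA stays open as well. The replication-dependent histone genes, whose transcripts as a class lack a poly(A) tail, had a median of 0.63 with 9 of 14 up and 2 down. They missed the same bound (camera, adjusted p = 0.145), which decides nothing here either. Their summed level was 123 ± 8.78 TPM in scrambled and 114 ± 5.88 TPM in Urod shRNA libraries (SD, n = 3 each). Most of that sum came from Hist1h1c (36.6 to 28.9 TPM), Hist1h2bc (36.6 to 34.5 TPM) and Hist3h2a (25.2 to 13.6 TPM). By mean, 11 of the 14 genes were higher in Urod shRNA libraries, so the lower sum does not speak against weaker selection. Rpph1, also without a tail, rose 3.06-fold, from 9.21 ± 5.78 to 28.2 ± 3.17 TPM (4.76-fold without scrambled replicate 3, which stood at 15.8 TPM), and Rmrp 3.08-fold, from 5.07 ± 2.29 to 15.6 ± 3.70 TPM. The abundant Mir6236 rose 1.42-fold, from 12979 ± 2482 to 18416 ± 1175 TPM, and microRNA and snoRNA rows together held 2.78% to 3.35% of TPM in scrambled and 3.47% to 3.69% in Urod shRNA libraries.

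The small rise of the respiratory chain and mitochondrial ribosomal protein genes, a median of 0.33 over 132 genes, could come from a trend with transcript length and GC content or from room left in the TPM total by the fall of the chaperones. Removing the trend left a median of 0.24. Complexes II to IV kept a median of 0.19, complex I and ATP synthase 0.16 and mitochondrial ribosomal proteins 0.35, with camera p under 0.05 unadjusted at the preset correlation (unadjusted p = 0.0867, 0.202 and 0.127 with an estimated correlation, and adjusted p = 0.149, 0.313 and 0.207 with it before the removal). Rescaling without the chaperones left 0.29. The medians kept argue against these as the whole cause, and the remaining difference between the hairpins may be biological, as a hypothesis.

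The wide difference could also stem from a gained or lost chromosome segment in one of the 2 cell populations. Adjacent genes had a Spearman correlation of 0.071 in their fold changes across 10030 genes, above the highest of 1000 permuted orders (0.029). A value this small argues only against shifts shared by neighbouring genes as the main part of the difference. Medians over 25 neighbouring genes ran from -0.40 to 0.44, within the permuted range of extremes (-0.51 to 0.51), though their SD (0.133) exceeded that of every permutation (mean 0.112). Small segments stay open, and so do segments whose shift lies within the permuted range, which the windows cannot show. Effects of a segment on genes outside it were not tested.

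In the authors' deposited pathway list, 451 genes were given. Its smallest absolute log2 fold change was 1.5027 and its smallest log2 CPM 0.00665. Bounds were inferred here as an absolute log2 fold change of at least 1.5, FDR under 0.05 and log2 CPM above 0. These inferred bounds held for 455 rows of the authors' deposited table. The 4 absent genes, Rsad2, Sparcl1, Neurl1b and C1qtnf3, were the only rows with a p above 0 but under the smallest normal double-precision number, and all 26 genes within the bounds with a p of exactly 0 were present.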
